A study of Drosophila melanogaster with 24 samples.

How the data were processed

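Gene expression was measured in whole Drosophila melanogaster embryos on 24 Affymetrix DrosGenome1 arrays, each hybridised with biotin-labelled cRNA made from total RNA. Per the labels, females carrying GAL4 under the armadillo promoter were crossed to 4 kinds of males. GAL4 is a yeast transcription factor that switches on any transgene placed behind its UAS binding sites, and the armadillo promoter is active in most cells of the embryo. The males carried UAS-NotchICD, UAS-Ras1V12, both transgenes, or none (w1118, the control). NotchICD is the intracellular part of the Notch receptor, which acts in the nucleus without ligand, and the Ras transgene encodes a constitutively active form of Ras85D, the GTPase that carries signals of receptor tyrosine kinases (RTKs). Embryos were frozen in 2 windows, from 5 h 45 min to 6 h 45 min after egg lay (early) and from 7 h to 8 h (late). Per the series' design text, RNA came from 3 independent experiments per cross and window, which gave 8 groups of 3 arrays.

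The deposited values are on a log2 scale, 1 per probe set and array. Per the submitters' processing notes, GCRMA and limma were used, and their versions are not given in the sources used here. GCRMA by default corrects background by probe sequence, normalises the arrays against each other by quantiles and summarises the probes of a set; with those defaults a shift shared by most genes of an array is removed before any comparison. Levels of dim probe sets are also drawn together near the floor, which understates the changes of genes absent in 1 of the groups compared. The table held 14010 probe sets, of which 44 Affymetrix control probe sets were left out. Among all probe sets, 12443 had 1 gene symbol, 327 had several and 1196 had none in the platform annotation; 49 symbols had no match in the RefSeq table and were kept as annotated. Probe sets with several symbols were tested but never named, and those without a symbol were counted only. No probe set of Notch itself, Ras85D, white or armadillo carried a name here, so the transgenes were not analysed here and the labels were not checked against them.

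A probe set was kept if its value was 5 or more in at least 3 of the 24 arrays, and a gene was represented by its probe set with the highest mean, which left 5736 rows to test (5020 with 1 symbol, 578 without and 138 with several). Between 5369 and 5677 probe sets per array reached a log2 value of 5, and array medians over all probe sets lay between 4.04 and 4.22. Arrays of 1 group differed from each other by 0.196 to 0.462 log2 units (root mean square over genes). Their number, 3 per group, limits the precision of every estimate.

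Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit on 8 group means, eBayes with the default prior, 16 residual and 4.09 prior degrees of freedom) over all 24 arrays, and 16 comparisons were taken from this fit. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Errors given with log2 changes are standard errors of the fit, with n = 3 arrays per group and 1 spread per gene pooled over all 8 groups. They are therefore the same in both windows, and understate the error for genes that vary more in the groups compared than elsewhere. Errors given with levels are standard deviations. The interaction compared the combined effect with the sum of both single effects on the log2 scale. The fit was tested on simulated data with known changes. In simulated data for Notch against control in the early window (5736 genes), 44.8% of genes changed by 0.5 log2 units, 89.6% of those changed by 1 and 100% of those changed by 2 were recovered, with 6 false calls among 162. For the simulated early interaction, the shares were 20.9%, 73.1% and 97% with 6 false calls among 133.

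Before the data were examined, 25 gene lists, the rule for named genes and the alternatives were fixed, except for the fits of 1 window at a time. Named were the 6 genes with the largest rise and the 6 with the largest fall among called genes whose 3 transgenic values all lay on 1 side of the 3 control values (5 and 5 in other comparisons, by call and size alone in interactions and in differences between windows). Also named were up to 4 called members of each list, or up to 2 members with the highest level where none was called, and the 5 genes with the largest shared change per combination of directions among those called for both Notch and Ras. Non-overlap of 3 values with 3 others occurs in 10% of genes by chance. Lists were tested against all other genes with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over 23 lists per comparison. Fry asked instead whether the genes of a list changed at all, on balance in 1 direction or in either, without comparing them with other genes. The lists covered the Enhancer of split and Bearded complexes, Notch pathway components, other Notch-responsive genes, proneural and neuroblast genes, neuronal differentiation, glia, RTK-Ras feedback and targets, RTK-Ras pathway components, mesoderm and muscle founders, muscle structure, trachea, epidermis and cuticle, cell death, cell cycle, hemocytes, amnioserosa, salivary gland, gut and endoderm, segmentation, heat shock, maternal and germline genes and housekeeping genes. The neuroectoderm column list had too few measured members for a set test, and the transgene list had none measured.

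The replicate numbers come from the labels. Deviations from group means of same-numbered arrays correlated above 0.1 in all 18 pairs of the early window (lowest 0.156, median 0.311) and all 18 of the late window (lowest 0.172, median 0.454), and 24 of 24 arrays had their closest array of another group in their window among those with their own number. The numbers were therefore taken to pair arrays within a window, which the labels' protocols do not state. Across windows 29 of 48 same-numbered pairs exceeded 0.1. A fit with the number within each window as a block (6 levels) is called the replicate block within window below, and one with 3 levels over both windows the replicate block.

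Alternatives comprised centring each array on its median, quantile normalisation over the kept probe sets, no filter, a filter at log2 7, eBayes with an intensity trend and robust prior, fits on only the groups compared, a minimum log2 change of 1, all probe sets, both replicate blocks, leaving out each array in turn, other set tests and 1 fit per window. Because Notch and Ras comparisons share their control arrays, 100 simulations of unchanged groups against shared controls gave the overlap and the covariance that sharing alone produces among independent arrays. The covariance where same-number arrays are paired was computed from products of their deviations from group means, a step chosen after the pairing was seen. The 3 control arrays per window could not be split into parts of at least 2 each. No array scan dates or batches are given in the sources used here, so batches were not tested.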

Results

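The series asked how the Notch and RTK-Ras pathways share transcriptional targets in the embryo. Both pathways were activated throughout Drosophila embryos, alone or together, and transcript levels were measured on 24 arrays of 5736 tested genes or probe sets. The 4 crosses are called control, Notch, Ras and combined below. Each was sampled with n = 3 arrays in an early window (5 h 45 min to 6 h 45 min after egg lay) and a late window (7 h to 8 h). Array medians lay between 4.04 and 4.22 log2 units, and 5369 to 5677 probe sets per array reached a log2 value of 5. The transgenes themselves were not analysed here, since no probe set of theirs carried a name. The plot of calls per comparison shows the 16 comparisons made in 1 limma fit.

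**Figure D1:**
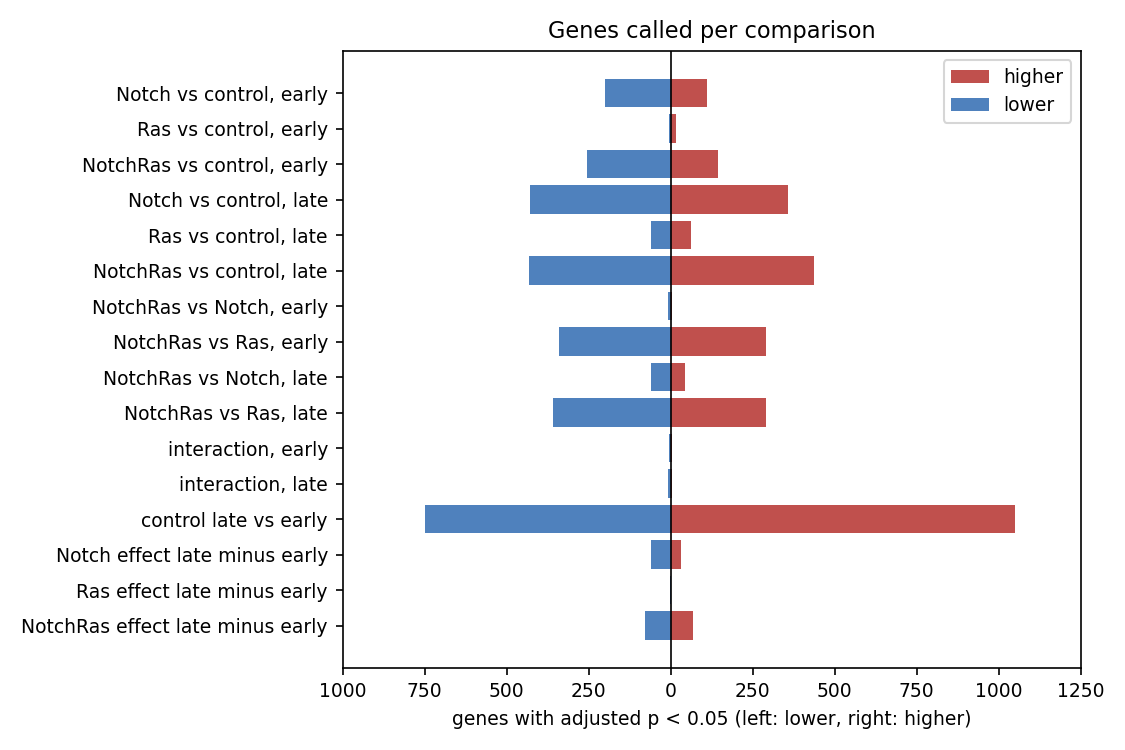
Number of genes called at an adjusted p under 0.05 in each of 16 comparisons (horizontal axis, genes; bars to the right higher, to the left lower). Control embryos changed 1798 genes between windows, activated Notch changed 311 early and 787 late, and activated Ras changed 21 early and 124 late. These counts rest on 1 spread per gene over both windows. With 1 fit per window they were 342 and 608 for Notch and 25 and 75 for Ras. The size of the increase from early to late thus depends on the fit.

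The change between windows in control embryos was described first, as the background for the transgene effects. Cell cycle genes were lower late as a list, and the genes that changed most were of several kinds. CG13159 rose by 5.21 ± 0.53 log2 units, the serpin gene Spn43Aa by 4.20 ± 0.41, verm, which encodes a chitin deacetylase of the tracheal and cuticle matrix, by 4.07 ± 0.45, CG9184 by 4.02 ± 0.99 and CG13920 by 3.98 ± 0.25. The scavenger receptor gene Sr-CII (-2.40 ± 0.24), the snoRNA host gene Uhg1 (-1.97 ± 0.21), the channel-family gene bib (-1.91 ± 0.24), the vitamin transporter gene Smvt (-1.90 ± 0.18) and E(spl)m5-HLH (-1.83 ± 0.26) fell. In total 1049 genes were higher and 749 lower in late control arrays. With each array centred on its median the share of higher genes was 44.7% against 58.3%, and 45.4% after quantile normalisation, so the balance of directions depends on scaling.

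All 10 measured muscle structural genes rose between windows in control embryos (10 adjusted over the list alone), among them the myosin light chain genes Mlc2 (3.52 ± 0.82) and Mlc1 (2.92 ± 0.87) and the troponin gene up (2.42 ± 0.74). The list was called with a preset correlation (adjusted p = 0.0013, camera), and lost the call at adjusted p = 0.31 with an estimated correlation. Late control arrays differed widely in these genes, with Mlc2 at 8.60 ± 2.26 log2 units (SD, n = 3), and Mlc1 and up lost their calls without late control replicate 1 or 2 (adjusted p up to 0.094 and 0.11) and in fits on only the arrays compared (0.072 and 0.092). Of 14 measured cell cycle genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone), including CycE (-1.17 ± 0.16), Mcm5 (-0.89 ± 0.16) and PCNA (-0.76 ± 0.14). The list moved lower as a set (adjusted p = 0.00047, and 0.015 with an estimated correlation). Among 12 hemocyte genes 7 rose (7 adjusted over the list alone), led by the type IV collagen genes vkg (1.92 ± 0.42) and Col4a1 (1.56 ± 0.36) and the crystal cell gene PPO1 (1.60 ± 0.23), with adjusted p = 0.029 and adjusted p = 0.19 with an estimated correlation. The glycolytic gene Gapdh1 rose by 0.92 ± 0.15. Beside it, the 3' minus 5' difference of the GAPDH control probe sets, which is read as a sign of RNA integrity but also follows the transcript, was 0.763 ± 0.183 log2 units in early and 3.17 ± 0.685 in late control arrays (SD, n = 3). That of actin was 0.608 ± 0.063 and 0.645 ± 0.262.

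Activated Notch in the early window lowered genes of nerve cell precursors and raised genes of the Enhancer of split complex. The zinc finger gene nerfin-1, expressed in nascent neurons, fell by 5.29 ± 0.26 log2 units, from 8.31 ± 0.32 to 3.03 ± 0.06 (SD, n = 3), a level near background. Another probe set of nerfin-1 gave a smaller fall (-1.89, adjusted p = 1.3e-06), so its size is uncertain. The neuroblast gene wor fell by 4.20 ± 0.15 log2 units, the bHLH genes tap by 3.65 ± 0.29 and Oli by 3.33 ± 0.19, CG43332 by 3.25 ± 0.29 and insb by 3.25 ± 0.15. The largest rises were those of CG13403 (4.81 ± 0.14), CG14572 (4.55 ± 0.31), wrapper, which encodes an immunoglobulin-family protein of midline glia (2.99 ± 0.19), Ect3 (2.73 ± 0.12), CG11498 (2.71 ± 0.28) and E(spl)m2-BFM (2.28 ± 0.17). The adjusted p was 6.6e-07 for CG11498 and smaller for the other 11 of these genes. All 12 stayed called without any 1 array. In all 111 genes rose and 200 fell. No scaling moved that balance by over 10 percentage points. The replicate block within window called 495 genes.

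Of 21 measured proneural and neuroblast genes 13 fell and 3 rose early with Notch (14 and 3 adjusted over the list alone), and the list moved lower (adjusted p = 3.8e-14, and 0.0021 with an estimated correlation). Besides nerfin-1, wor and tap, the asymmetric division gene insc fell by 3.16 ± 0.14 log2 units, while the transcription factor genes dpn (1.55 ± 0.27) and esg (1.53 ± 0.14) of the same list rose. Enhancer of split genes, which encode bHLH repressors and Bearded-family proteins, rose in 8 of 10 cases (9 adjusted over the list alone), with E(spl)m2-BFM followed by Kaz-m1 (1.97 ± 0.13) and E(spl)malpha-BFM (1.25 ± 0.15). The set test gave adjusted p = 8.1e-18, and 0.0033 with an estimated correlation. Amnioserosa genes fell in 4 of 10 cases (6 adjusted over the list alone), including ush (-0.94 ± 0.19), Kr (-0.93 ± 0.20) and Doc3 (-0.81 ± 0.14), with adjusted p = 4.7e-05, and 0.012 with an estimated correlation. RTK-Ras feedback and target genes rose in 4 of 9 cases and fell in 1 (4 and 1 adjusted over the list alone). The head gap gene oc (1.61 ± 0.16) and the ETS repressor gene aop (0.90 ± 0.10) were among those higher and hkb was lower (-0.62 ± 0.13), with adjusted p = 3.5e-05, and 0.019 with an estimated correlation.

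Smaller groups moved in part with early Notch. The neuroectoderm column genes ind (-1.23 ± 0.17) and Dr (-1.10 ± 0.18), the 2 measured of 5, both fell (2 adjusted over the list alone). Of 5 neuronal differentiation genes the RNA-binding protein gene elav fell (-1.37 ± 0.31) and the RTK ligand gene jeb rose (0.98 ± 0.17), and the list was not called (adjusted p = 0.44; 1 rose and 3 fell adjusted over the list alone). Segmentation genes fell in 3 of 13 cases and rose in 1 (4 and 3 adjusted over the list alone), and the pair-rule genes hry (-1.32 ± 0.15) and ftz (-1.17 ± 0.19) were among the lower ones (adjusted p = 0.50). Of 5 cell death genes 2 fell, led by egr (-0.88 ± 0.15), also 2 adjusted over the list alone (adjusted p = 0.10). Gut and endoderm genes grn (-0.85 ± 0.18) and hkb fell among 8 (3 adjusted over the list alone, adjusted p = 0.17). The epidermal gene neo rose (0.63 ± 0.18) among 5 measured (1 adjusted over the list alone), where adjusted p = 0.027, and adjusted p = 0.15 with an estimated correlation. neo lost its call without control replicate 2 or 3 or Notch replicate 1 or 2 (adjusted p up to 0.25) and in fits on only the arrays compared (0.12). None of 4 heat shock genes, 6 maternal and germline genes or 3 housekeeping genes was called early, with or without adjustment over the list alone (adjusted p = 0.44, 0.77 and 0.70).

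**Figure D2:**
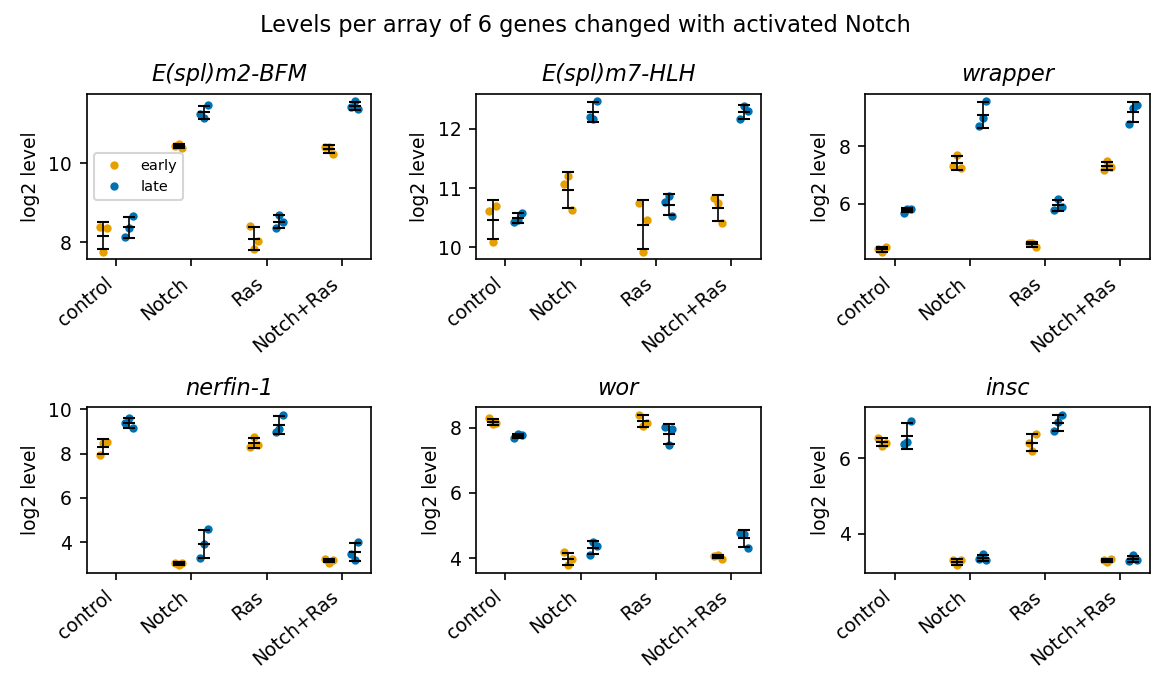
Log2 level (vertical axis) of 6 genes in each array, by cross (horizontal axis) and window (orange early, blue late), with points for arrays and black bars for mean ± SD, n = 3. E(spl)m2-BFM lay at 8.16 ± 0.35 in early control and 10.4 ± 0.05 in early Notch arrays, nerfin-1 at 8.31 ± 0.32 and 3.03 ± 0.06, and the combined arrays lay beside the Notch arrays for both.

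With Notch in the late window, Enhancer of split genes were again higher and nerve cell precursor genes lower. CG14572 (4.47 ± 0.31), CG13403 (4.44 ± 0.14), CG14567 (3.77 ± 0.15), wrapper (3.31 ± 0.19), CG7860 (3.18 ± 0.25) and E(spl)m2-BFM (2.92 ± 0.17) rose most. nerfin-1 fell by 5.47 ± 0.26 log2 units (-2.34 at its other probe set, adjusted p = 3.4e-08), CG13159 by 4.73 ± 0.53 log2 units, CG13920 by 4.60 ± 0.25, tap by 4.54 ± 0.29, CG14756 by 4.26 ± 0.47 and Oli by 4.21 ± 0.19. CG13159 and CG13920 were also among the 5 genes that rose most between windows in control embryos. Of 787 genes called, 357 were higher and 430 lower, a balance that turned to 460 higher and 404 lower after array median centring and 477 and 425 after quantile normalisation. The adjusted p was 1.4e-06 for CG13159 and smaller for the other 11 genes named. The replicate block within window called 1231 genes, and fits on only the 6 arrays compared called 520.

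Enhancer of split genes rose in 9 of 10 cases late with Notch (9 adjusted over the list alone), with E(spl)m4-BFM at 1.91 ± 0.20 and Kaz-m1 at 1.89 ± 0.13 (adjusted p = 4.5e-15, and 0.014 with an estimated correlation). All 3 measured Bearded complex genes rose (3 adjusted over the list alone), Ocho by 1.15 ± 0.23, Tom by 0.65 ± 0.11 and Brd by 0.64 ± 0.14 (adjusted p = 0.0024, and 0.043 with an estimated correlation). Proneural and neuroblast genes fell in 13 of 21 cases and rose in 3 (14 and 3 adjusted over the list alone), with wor at -3.43 ± 0.15 and insc at -3.23 ± 0.14 (adjusted p = 2.2e-06, and 0.040 with an estimated correlation). The neuronal RNA-binding protein genes fne (-2.32 ± 0.27) and elav (-1.47 ± 0.31) fell among 5 neuronal differentiation genes (3 adjusted over the list alone, adjusted p = 0.074). Glial genes went both ways, with wrapper and 1 other higher and repo (-1.09 ± 0.19), gcm (-0.72 ± 0.13), htl (-1.04 ± 0.23) and 1 other lower of 9 (2 and 5 adjusted over the list alone, adjusted p = 0.38). Of 7 other Notch-responsive genes Him rose (1.55 ± 0.17) and 2 fell, Hey most (-1.73 ± 0.27) (2 and 3 adjusted over the list alone, adjusted p = 0.69). Among 15 Notch pathway components the ligand gene Delta (0.66 ± 0.14) and dx (0.47 ± 0.10) rose and 1 other fell, without a call of the list (3 and 1 adjusted over the list alone, adjusted p = 0.32). Delta lost its call in fits on only the arrays compared (adjusted p = 0.05002).

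Genes of other tissues also moved late with Notch. Hemocyte genes fell in 8 of 12 cases and rose in 1 (8 and 1 adjusted over the list alone), including vkg (-1.77 ± 0.42) and PPO1 (-1.19 ± 0.23), with adjusted p = 0.0076 and adjusted p = 0.084 with an estimated correlation. vkg lost its call in fits on only the arrays compared (adjusted p = 0.061) and with 1 fit per window (0.059). Col4a1 lost it in the same fits (0.13 and 0.11) and without control replicate 1 or 2 or Notch replicate 3 (up to 0.11). Control replicate 3 was low in both genes, at 5.18 for vkg (7.04 and 7.02 in the others) and 6.13 for Col4a1 (7.88 and 7.91). Salivary gland genes PH4alphaSG2 (-1.23 ± 0.22), hkb (-1.13 ± 0.13) and sage (-0.64 ± 0.11) fell, 3 of 6 (3 adjusted over the list alone), with adjusted p = 0.0081, and 0.043 with an estimated correlation. Amnioserosa genes fell in 5 of 10 cases (5 adjusted over the list alone), led by Kr (-2.39 ± 0.20), where adjusted p = 0.018 and adjusted p = 0.10 with an estimated correlation. Of 10 muscle structural genes Prm and Act87E fell (6 adjusted over the list alone), with adjusted p = 0.0032 and adjusted p = 0.29 with an estimated correlation. Prm was low in control replicate 3 (4.42 against 6.52 and 6.34). It lost its call without any 1 array but that (adjusted p up to 0.15), with 1 fit per window (0.14) and in fits on only the arrays compared (0.22). Act87E lost its call without control replicate 2 or Notch replicate 2 or 3 (up to 0.079). Tracheal genes rose in 5 of 11 cases and fell in 1 (5 and 1 adjusted over the list alone), including esg (1.20 ± 0.14) and the FGF receptor gene btl (1.11 ± 0.18), with adjusted p = 0.021 and adjusted p = 0.15 with an estimated correlation. Of 16 RTK-Ras pathway components 5 rose and none fell (7 adjusted over the list alone), among them the ligand genes ths (1.13 ± 0.22) and pyr (0.40 ± 0.10, not called in fits on only the arrays compared, adjusted p = 0.076), with adjusted p = 0.0024 and adjusted p = 0.084 with an estimated correlation. Of 5 cell death genes egr, a tumour necrosis factor gene, fell (-2.19 ± 0.15) and skl rose (1.21 ± 0.24), and 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.62). Gapdh1 fell (-0.69 ± 0.15), and the GAPDH 3' minus 5' difference was 1.61 ± 0.146 in these arrays against 3.17 ± 0.685 in late control arrays (SD, n = 3).

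Activated Ras in the early window changed few genes. CG8066 (1.51 ± 0.17), CG31445 (1.48 ± 0.22), M6, a proteolipid-family gene (1.24 ± 0.16), the EBF-family gene kn (1.12 ± 0.25), the FGF receptor gene htl (1.08 ± 0.23) and the tumour necrosis factor receptor gene wgn (1.01 ± 0.17) rose. Uhg1 (-2.38 ± 0.21), the odorant receptor gene Or71a (-1.36 ± 0.16), CG8745 (-1.10 ± 0.18), Cpr5C (-0.85 ± 0.18), Polr1E (-0.43 ± 0.09) and the pair-rule gene odd (-0.41 ± 0.09) fell. Of the 9 measured RTK-Ras feedback and target genes only aop was called (0.58 ± 0.10, adjusted p = 0.0083), against 4 adjusted over the list alone. The list moved higher as a set (adjusted p = 2.6e-08, and 0.0070 with an estimated correlation). Mesoderm and muscle founder genes moved higher as a set, with htl called among 12 (6 higher and 2 lower adjusted over the list alone), at adjusted p = 0.00023 and adjusted p = 0.091 with an estimated correlation. In all 15 genes rose and 6 fell. kn (adjusted p = 0.050) and htl (0.047) lost their calls without any 1 of the 6 arrays, with adjusted p up to 0.30 and 0.20, as did Polr1E (up to 0.24) and odd (up to 0.26). Cpr5C lost its call without control replicate 1 or 3 or any Ras replicate (up to 0.22), and aop without control replicate 3 or Ras replicate 1 or 2 (up to 0.091). In fits on only the arrays compared, CG8745 (0.10), Cpr5C (0.061), Polr1E (0.096), odd (0.16) and aop (0.061) were not called. odd was also lost after array median centring (0.11) or quantile normalisation (0.076). The count was 13 without control replicate 1, 10 without control replicate 3, and 12 without Ras replicate 1 or 2, while the replicate block within window called 44.

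Ras activation raised genes of RTK feedback and of mesoderm in the late window. CG31445 rose by 2.66 ± 0.22 log2 units, followed by the MyoD-family gene nau (1.77 ± 0.25), wgn (1.70 ± 0.17), the tendon gene Lrt (1.62 ± 0.22), the mesoderm determinant gene twi (1.50 ± 0.13) and htl (1.43 ± 0.23). Or71a (-2.22 ± 0.16), CG7296 (-1.78 ± 0.21), the verprolin gene Vrp1 (-1.59 ± 0.18), gol (-1.46 ± 0.20), and the sugar metabolism genes fbp (-1.43 ± 0.28) and Pgm1 (-1.41 ± 0.16) fell. The adjusted p was 0.0050 for fbp and smaller for the other 11 genes. Of 124 genes called, 63 were higher and 61 lower, a share of 50.8% higher that became 40.1% with either array median centring or quantile normalisation. Fits on only the 6 arrays compared called 22 genes and ended the calls of nau (adjusted p = 0.075), Lrt (0.066), htl (0.16) and fbp (0.16) among these 12. With 1 fit per window 75 genes were called, without fbp (0.099), and the replicate block within window called 281.

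The secreted EGF receptor inhibitor gene aos (1.15 ± 0.21), the RTK inhibitor gene sty (1.08 ± 0.14), edl (0.96 ± 0.16) and aop (0.78 ± 0.10) led the 5 of 9 RTK-Ras feedback and target genes that rose late with Ras (6 adjusted over the list alone), with adjusted p = 2.3e-09, and 0.0023 with an estimated correlation. Mesoderm and muscle founder genes rose in 7 of 12 cases (8 adjusted over the list alone, with 1 lower), and besides nau, twi and htl the muscle repressor gene Him rose by 1.12 ± 0.17 (adjusted p = 1.2e-11, and 0.0023 with an estimated correlation). RTK-Ras pathway components btl (0.94 ± 0.18), spi (0.57 ± 0.11) and 1 other rose among 16 (3 adjusted over the list alone), where adjusted p = 0.011 and adjusted p = 0.18 with an estimated correlation. Delta rose by 1.19 ± 0.14, the only called gene of the Notch pathway list (2 adjusted over the list alone, adjusted p = 0.0061, and adjusted p = 0.14 with an estimated correlation). Of the Enhancer of split genes E(spl)m6-BFM alone rose (0.77 ± 0.20; 1 adjusted over the list alone), with adjusted p = 0.037 and adjusted p = 0.42 with an estimated correlation. E(spl)m6-BFM lost its call without any 1 array but control replicate 3 (adjusted p up to 0.16) and after array median centring (0.056). Of 21 proneural and neuroblast genes 2 rose (5 adjusted over the list alone), with adjusted p = 0.00048 and adjusted p = 0.14 with an estimated correlation. In fits on only the 6 arrays compared, aos (adjusted p = 0.10), sty (0.060), aop (0.053), Him (0.10), btl (0.053), spi (0.17) and E(spl)m6-BFM (0.096) lost their calls. No hemocyte, amnioserosa, salivary gland, cell cycle or heat shock gene was called late with Ras. The GAPDH 3' minus 5' difference was 2.45 ± 0.456 in these arrays (SD, n = 3).

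**Figure D3:**
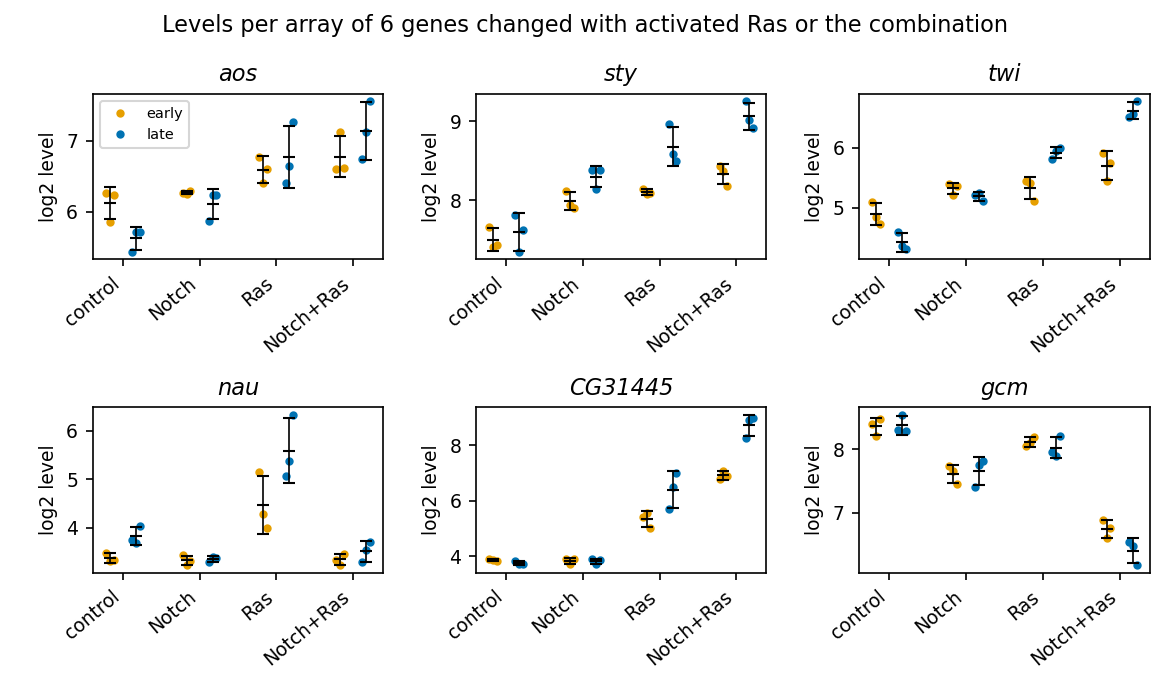
Log2 level (vertical axis) of 6 genes in each array, by cross (horizontal axis) and window (orange early, blue late), with points for arrays and black bars for mean ± SD, n = 3. Late CG31445 lay at 3.75 ± 0.07 in control, 3.82 ± 0.09 in Notch, 6.40 ± 0.65 in Ras and 8.72 ± 0.39 in combined arrays, and late gcm at 8.38 ± 0.15, 7.66 ± 0.22, 8.02 ± 0.16 and 6.40 ± 0.20.

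Embryos with both transgenes resembled Notch embryos at their largest changes in the early window. CG13403 (4.39 ± 0.14), CG14572 (4.01 ± 0.31), wrapper (2.89 ± 0.19), Ect3 (2.56 ± 0.12) and CG11498 (2.53 ± 0.28) rose, and CG31445, unchanged by Notch alone within the error (3.83 ± 0.11 against 3.86 ± 0.04 log2 units, SD, n = 3), rose by 3.06 ± 0.22. nerfin-1 (-5.15 ± 0.26, and -1.81 at its other probe set), wor (-4.14 ± 0.15), tap (-3.71 ± 0.29), CG43332 (-3.29 ± 0.29), Oli (-3.14 ± 0.19) and insc (-3.12 ± 0.14) fell. Of 399 genes called (145 higher, 254 lower), 250 were also called in the same direction for Notch and 11 for Ras, and 144 were called for neither. Of those 144, only 1 was called in the interaction, so most show no called departure from the sum of single effects. Enhancer of split genes rose in 5 of 10 cases (8 adjusted over the list alone; adjusted p = 2.4e-09, and 0.022 with an estimated correlation). Proneural and neuroblast genes fell in 12 of 21 and rose in 3 (15 and 3 adjusted over the list alone; adjusted p = 1.9e-13, and 0.0025 with an estimated correlation). Salivary gland genes fell in 3 of 6 cases, among them hkb (-0.72 ± 0.13) and pip (-0.65 ± 0.15) (3 adjusted over the list alone; adjusted p = 0.0017, and 0.015 with an estimated correlation). pip lost its call after quantile normalisation (-0.45, adjusted p = 0.081). The replicate block within window called 729 genes and fits on only the 6 arrays compared 613.

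In late combined embryos 438 genes were higher and 431 lower than in control. Among named genes CG31445 rose most (4.98 ± 0.22), and CG13403 (4.51 ± 0.14), CG14572 (4.18 ± 0.31), CG14567 (3.96 ± 0.15), wrapper (3.41 ± 0.19) and CG7860 (3.12 ± 0.25) followed. nerfin-1 fell by 5.84 ± 0.26 log2 units (-2.58 at its other probe set, adjusted p = 6.6e-09), with CG13159 (-5.62 ± 0.53), CG13920 (-4.74 ± 0.25), tap (-4.48 ± 0.29), CG14756 (-4.26 ± 0.47) and Oli (-4.08 ± 0.19) next. All 10 Enhancer of split genes rose (10 adjusted over the list alone; adjusted p = 1.7e-16, and 0.0048 with an estimated correlation). RTK-Ras feedback and target genes rose in 7 of 9 cases with hkb lower (7 and 1 adjusted over the list alone; adjusted p = 5.4e-06, and 0.012 with an estimated correlation). They included oc (1.80 ± 0.16), aos (1.52 ± 0.21) and sty (1.46 ± 0.14). Proneural and neuroblast genes fell in 10 of 21 and rose in 4 (12 and 5 adjusted over the list alone), where adjusted p = 9.7e-05 and adjusted p = 0.0502 with an estimated correlation. Salivary gland genes fell in 4 of 6 cases (4 adjusted over the list alone), led by PH4alphaSG2 (-2.07 ± 0.22; adjusted p = 6.9e-05, and 0.0048 with an estimated correlation). Hemocyte genes fell in 5 of 12 and rose in 1 (8 and 1 adjusted over the list alone), with gcm at -1.98 ± 0.13 and PPO1 at -1.23 ± 0.23 (adjusted p = 0.00020, and 0.028 with an estimated correlation). Muscle structural genes fell in 6 of 10 (10 adjusted over the list alone), at adjusted p = 6.4e-06 and adjusted p = 0.13 with an estimated correlation. These calls rested on the control arrays, of which replicate 3 was low (Mlc1 at 4.55 against 8.78 and 9.01 log2 units). Without control replicate 1 or 2 the calls of Mlc2, up, Prm and bt were lost, while without control replicate 3 all 4 were kept. Mlc2 was also lost without combined replicate 1 or 3, Prm without combined replicate 2, and up and bt without any combined replicate (adjusted p up to 0.15 for Mlc2, 0.19 for up, 0.13 for Prm and 0.28 for bt). All 4 were lost in fits on only the arrays compared (0.15, 0.18, 0.19 and 0.22). Of the calls, 562 were shared in direction with Notch and 87 with Ras, and 272 genes were called for neither. Of those 272, only 2 were called in the interaction, so most show no called departure from the sum of single effects. Fits on only the 6 arrays compared called 558 genes.

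Adding Ras to activated Notch changed 13 genes early and 105 late. Early, CG31445 (3.09 ± 0.22), M6 (1.58 ± 0.16), the zinc transporter gene ZnT77C (0.92 ± 0.11), CG10492 (0.60 ± 0.10) and mdlc (0.55 ± 0.11) were higher in combined than in Notch embryos. The acyltransferase gene Dgat2 (-1.74 ± 0.20), CG13315 (-1.31 ± 0.22), zfh1 (-0.95 ± 0.18), CG9119 (-0.89 ± 0.14) and the glial and hemocyte regulator gene gcm (-0.87 ± 0.13) were lower. Late, CG31445 (4.91 ± 0.22), wgn (1.52 ± 0.17), Kr (1.45 ± 0.20), twi (1.44 ± 0.13) and E(spl)m6-BFM (1.39 ± 0.20) were higher, and CG13315 (-2.61 ± 0.22), CG5080 (-1.97 ± 0.35), Dgat2 (-1.96 ± 0.20), Kah (-1.87 ± 0.18) and gol (-1.83 ± 0.20) lower. Mesoderm and muscle founder genes rose late in 7 of 12 cases (8 higher and 1 lower adjusted over the list alone; adjusted p = 7.0e-08, and 0.015 with an estimated correlation). RTK-Ras feedback and target genes aos (1.03 ± 0.21) and sty (0.76 ± 0.14) rose, 2 of 9 (6 adjusted over the list alone; adjusted p = 2.6e-05, and 0.015 with an estimated correlation). aos lost its call without combined replicate 3 (adjusted p = 0.077). Segmentation genes moved lower late with hry (-1.55 ± 0.15) as the called member (2 adjusted over the list alone; adjusted p = 0.00065, and 0.015 with an estimated correlation).

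The early calls of combined against Notch embryos were 5 higher and 8 lower, a share of 38.5% higher that was 21.1% after array median centring and 26.3% after quantile normalisation. They numbered 23 without Notch replicate 3, 8 without combined replicate 1, and 46 with the replicate block within window. mdlc and zfh1 lost their calls without Notch replicate 1 or 2 or combined replicate 1 or 3 (adjusted p up to 0.27 and 0.17). CG13315 lost its call without combined replicate 1 (0.066). In fits on only the arrays compared, 6 of the 10 genes named early were not called, CG10492 (0.52), mdlc (0.53), CG9119 (0.32), zfh1 (0.15), CG13315 (0.11) and gcm (0.10). Late, Kr (0.054), CG5080 (0.074), aos (0.12) and sty (0.054) were not. The late calls were 44 higher and 61 lower, and numbered 66 without Notch replicate 2, 59 without Notch replicate 3, 68 without combined replicate 3, 34 in fits on only the arrays compared, 55 with 1 fit per window and 211 with the replicate block within window.

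Combined embryos against Ras embryos showed what Notch added. The genes that moved most were those of Notch against control, with CG13403 at 4.39 ± 0.14 early and 4.52 ± 0.14 late, wrapper at 2.72 ± 0.19 and 3.24 ± 0.19, nerfin-1 at -5.32 ± 0.26 and -5.75 ± 0.26 (-1.58 and -2.64 at its other probe set), and tap at -4.29 ± 0.29 and -4.63 ± 0.29. Early, CG14572 (2.89 ± 0.31), CG11498 (2.46 ± 0.28) and Ect3 (2.40 ± 0.12) were also higher and wor (-4.15 ± 0.15), Oli (-3.27 ± 0.19) and insc (-3.12 ± 0.14) lower. Enhancer of split genes rose in 7 of 10 cases early and all 10 late (7 and 10 adjusted over the list alone), with adjusted p = 0.038 and 0.0063 with an estimated correlation. Proneural and neuroblast genes fell in 15 of 21 early and 12 late (17 and 13 adjusted over the list alone), with adjusted p = 0.0012 and 0.0066 with an estimated correlation. In all 291 genes rose and 341 fell early, and 290 rose and 358 fell late. The early count of 632 was 415 without combined replicate 1, 420 without combined replicate 3, 411 without Ras replicate 1, 376 without Ras replicate 2 and 1128 with the replicate block within window. The late count of 648 was 351 in fits on only the arrays compared and 1072 with that block.

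The interaction asked whether the combined effect departed from the sum of the single effects, and few genes passed. Or71a, which fell with Ras alone, was higher than the sum by 1.29 ± 0.23 early and 1.97 ± 0.23 late. CG31445 was called as well (1.60 ± 0.32 and 2.25 ± 0.32), but lay near background in control and Notch arrays, where a lowering by Notch alone could not be seen. Its sum is therefore not known, and what was measured is a higher level in combined than in Ras arrays (8.72 ± 0.39 against 6.40 ± 0.65 log2 units late, SD, n = 3). Dgat2 (-1.68 and -1.81) lay near background in control and Ras arrays, where a lowering by Ras alone could not be seen, so its sum is not known either. It rose with Notch alone (5.79 ± 0.55 against 3.75 ± 0.06 late) and stood at 3.83 ± 0.13 in late combined arrays. Early, CG10492 was also higher (0.69 ± 0.14) and CG8066 lower (-1.65 ± 0.25). Late, the acyl-CoA synthetase gene bgm was higher (1.17 ± 0.22), and the GATA factor gene grn (-1.28 ± 0.25), Su(Tpl) (-1.22 ± 0.20), CG3036 (-1.06 ± 0.17), Delta (-0.996 ± 0.194) and gcm (-0.91 ± 0.19) lower. CG13315 was called late (-1.65 ± 0.31) but lay near background in late Ras arrays (4.23 to 4.61 log2 units), where a deeper fall could not be seen, so its sum is not known. In all 4 genes were higher and 4 lower early, and 4 higher and 9 lower late, and no list was called with an estimated correlation. Among the higher ones, Uhg1 early (2.42 ± 0.29) and CG13064 late (1.32 ± 0.16) could not have shown the sum, since they lay near background with Notch and with both transgenes, so their calls say nothing about an interaction. Uhg1 stood at 3.96 to 3.99 log2 units in all 3 early transgenic groups, and CG13064 at 4.01 to 4.24 in late Notch and 3.98 to 4.41 in late combined arrays. Over genes called for either transgene, the slope of the combined effect on the sum of single effects was 0.851 early (323 genes) and 0.851 late (839 genes). The genes were chosen by their single effects, the same control arrays enter both sides, and the floor limits some levels. This slope therefore does not show a departure from the sum.

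Interaction calls depended on single arrays and on scaling. The early count was 3 without control replicate 3, 5 without Notch replicate 1, 13 without Notch replicate 3 and 4 without Ras replicate 2, and the share of higher calls was 25% after either scaling against 50%. Or71a lost its early call without control replicate 2 or 3, Notch replicate 1, combined replicate 3 or Ras replicate 1 or 2 (adjusted p up to 0.065), CG10492 without any array but Notch replicates 2 and 3 and combined replicate 3 (up to 0.18). Dgat2 lost it without control replicate 3 (0.05003). After quantile normalisation Or71a (0.10), CG10492 (0.10) and Dgat2 (0.055) were not called early. CG31445 lost its early call (adjusted p = 0.049) without any 1 of the 12 arrays (up to 0.13) and after array median centring (0.062) or quantile normalisation (0.095), and another probe set of CG8066 gave -1.42 without a call (adjusted p = 0.27). The late count was 7 without control replicate 3 or combined replicate 3, and gcm lost its late call (adjusted p = 0.039) under the replicate block (0.051). Without 1 array gcm was called only when that array was control replicate 2, Notch replicate 1, combined replicate 1 or Ras replicate 2 (otherwise up to 0.16), and grn only when it was a Ras array (otherwise up to 0.091). CG13315 lost its late call without control replicate 3 or combined replicate 1 or 3 (up to 0.077). bgm lost it without control replicate 2 or 3, Notch replicate 1 or 2 or combined replicate 2 or 3 (up to 0.10). Delta lost it without control replicate 3, Notch replicate 1 or 3, combined replicate 2 or 3 or Ras replicate 1 or 3 (up to 0.11). In fits on only the groups compared, late calls ended for CG31445 (adjusted p = 0.073), Dgat2 (0.062), CG13064 (0.057), CG13315 (0.24), grn (0.24), bgm (0.28), Delta (0.29) and gcm (0.31), and the early call of CG10492 (0.27). With the replicate block within window 36 genes were called early and 28 late.

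Genes called for both Notch and Ras were counted as candidates for common targets. In the early window 9 genes were called for both, 5 higher in both (0.29 for independent lists), 2 lower with Notch and higher with Ras (0.523) and 2 lower in both (0.209). They included wgn (0.79 with Notch, 1.01 with Ras), aop (0.90 and 0.58), CG8066 (0.92 and 1.51), kn (-1.82 and 1.12), Uhg1 (-2.40 and -2.38) and CG8745 (-1.70 and -1.10). Late, 72 genes were called for both, 23 higher in both (3.92 for independent lists), 30 lower in both (4.57), 13 lower with Notch and higher with Ras (4.72) and 6 higher with Notch and lower with Ras (3.80). Unchanged groups against the same controls, simulated 100 times with the spread of the whole fit, gave 0 shared calls in each window. With the larger spread of the late window itself, 0.18 genes on average (at most 2) were called for both in the same direction. Unchanged groups are hardly called at all (1.98 Notch and 1.4 Ras late calls on average), so these counts say nothing about overlap among changed genes. Another probe set of CG8066 gave 0.468 with Notch and was not called (adjusted p = 0.63). Early kn was lost without any 1 of the 6 Ras and control arrays (adjusted p up to 0.30), and aop without control replicate 3 or Ras replicate 1 or 2 (up to 0.091). The overlap was 4 early without control replicate 3 or Ras replicate 2, and 46 late without control replicate 2. It was 23 early and 171 late with the replicate block within window, and 4 and 12 in fits on only the arrays compared. With the called effects kept, those of Ras shuffled over genes and the controls shared, 14.81 genes on average moved the same way late, against 53 observed. Genes and arrays were drawn independently there, so deviations that they share could not arise.

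Late genes higher with both transgenes included Lrt (1.49 with Notch and 1.62 with Ras), Him (1.55 and 1.12), rau (0.99 and 1.33) and btl (1.11 and 0.94). Lower with both were CG7296 (-1.94 and -1.78), fbp (-1.83 and -1.43) and CG13064 (-2.09 and -1.33). Genes lower with Notch and higher with Ras included kn (-2.66 and 1.11), the myoblast fusion gene rols (-1.40 and 1.09) and htl (-1.04 and 1.43). The Ras call of kn was lost without control replicate 1 or Ras replicate 2 or 3 (adjusted p up to 0.095). In fits on only the arrays compared, the Ras calls of kn (0.47), rols (0.080), htl (0.16), Lrt (0.066), Him (0.10), btl (0.053), fbp (0.16) and Cpr5C (0.16) were lost. The cuticle gene Cpr5C (1.09 and -1.05) was among those higher with Notch and lower with Ras. Across 5736 genes, which are not independent replicates, Notch and Ras effects correlated at r = 0.216 early (rho 0.314) and 0.175 late (rho 0.240). Shared controls alone, simulated with independent arrays, gave r of 0.499 and 0.502. These values are set by the equal group sizes and hold only where no gene changes, so the observed r cannot be judged against them. The covariance was 0.0143 early against 0.0164 simulated and 0.0210 late against 0.0165. With the spread of each window itself the simulated values were 0.0138 and 0.0229, and both differences changed sign (from -0.0022 to 0.0005 early and from 0.0045 to -0.0020 late). Where the replicate numbers pair the arrays, deviations between replicates alone give 0.0055 early and 0.0151 late, below the observed values. From deviations of the control arrays alone, with arrays taken as independent, the value was 0.0096 early, also below the observed one, and 0.0268 late, above it. Whether the late effects vary together beyond the shared controls thus rests on the pairing, which the labels do not state. Early it rests on the spread used, since the observed value lay below that simulated with the spread of the whole fit. Without Notch replicate 1 the early r was 0.0856 and without control replicate 1 it was 0.285. The late r was 0.258 without control replicate 1, 0.310 without control replicate 3 and 0.111 without Ras replicate 3.

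**Figure D4:**
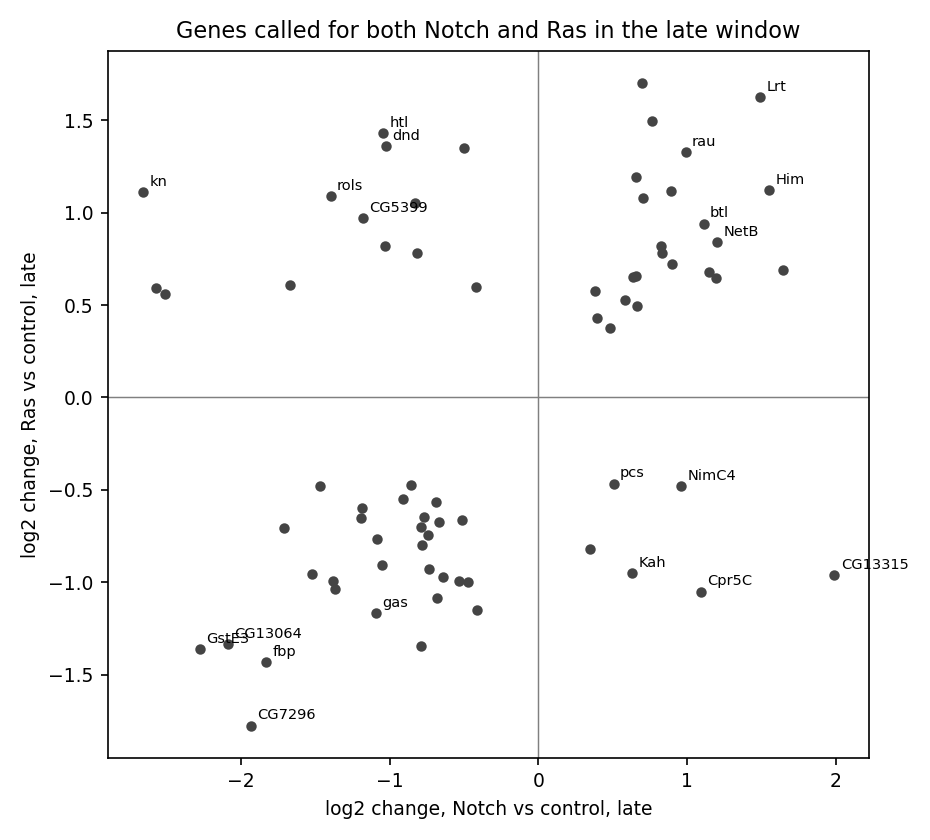
Log2 change with Notch (horizontal axis) against log2 change with Ras (vertical axis), late window, for the 72 genes called in both comparisons (points, estimates of the fit; names for up to 5 per combination of directions). Of these, 23 lie in the upper right, 30 in the lower left, 13 in the upper left and 6 in the lower right quadrant.

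Effects of each transgene were also compared between windows by the difference of late and early effects. The Notch effect differed for 92 genes (31 higher late, 61 lower), the Ras effect for 4 (2 and 2) and the combined effect for 146 (67 and 79). CG14567 rose more with Notch in the late window (difference 2.23 ± 0.22), as did the Wnt ligand gene Wnt6 (2.03 ± 0.22), while CG13920 differed by -3.82 ± 0.35 and was itself low in early control arrays (3.85 ± 0.19 log2 units, SD, n = 3), so an early fall could hardly be measured. For Ras, twi differed by 1.06 ± 0.18 (called unless early control replicate 1, late control replicate 2 or 3, early Ras replicate 3 or late Ras replicate 2 or 3 was left out, adjusted p up to 0.073) and PheRS-m by -1.14 ± 0.17. Neither was called in fits on only the groups compared (0.077 for both). The mesoderm and muscle founder list was called for the difference of Ras effects (adjusted p = 9.0e-07, and 0.029 with an estimated correlation), with 1 of 12 genes called (3 adjusted over the list alone). The Notch count was 59 without early control replicate 3. The Ras count was 9 without late control replicate 1 and 2 without late Ras replicate 2. The combined count was 86 without early control replicate 1, 84 without early control replicate 3, 89 without late control replicate 2, 97 without early combined replicate 2, and 96 without early or late combined replicate 3. With the replicate block within window the counts were 222, 18 and 338. The Ras share of higher calls was 28.6% after array median centring and 15.4% after quantile normalisation, against 50%.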

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

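In this part, the tests on splits that part all same-number pairs were chosen after the other regroupings were seen, and the other tests before. A difference between the late and the early effect of the same transgene was tested directly in the limma fit, and the genes with the largest differences are given for each transgene. Single arrays standing apart within their group of 3 were not tested.

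With activated Notch the effect of 92 genes differed between windows. CG14567 was raised more late (difference 2.23 ± 0.22 log2 units), as were the Wnt ligand gene Wnt6 (2.03 ± 0.22) and the transporter gene dmGlut (1.44 ± 0.18). The difference of the proneural gene ac (1.30 ± 0.19) was an early fall that was absent late, since ac stood at 5.10 in early and 3.76 in late control arrays and little was left to lower. The difference of Uhg1 (2.05 ± 0.29) goes with its early control level of 6.36 ± 0.69 log2 units, above every other group. CG13159 (-3.95 ± 0.75), CG13920 (-3.82 ± 0.35), CG14756 (-3.50 ± 0.67), CG14110 (-3.16 ± 0.76) and JhI-26 (-2.57 ± 0.32) had lower effects late. In early control arrays these 5 genes were low (2.22 to 2.44 log2 units for CG14110, 4.18 to 4.52 for JhI-26, 3.65 to 4.03 for CG13920, 4.16 to 5.08 for CG14756 and 4.90 to 5.88 for CG13159). An early fall of the late size could not have been seen, so these differences do not show that Notch acted on them late only. CG14110 lost its call without any 1 of 10 arrays, the exceptions being late control replicate 3 and late Notch replicate 1 (adjusted p up to 0.10), and in fits on only the groups compared (0.051). The count was 59 without early control replicate 3. Of 100 random regroupings of the arrays, 1 (the real one) gave as many genes, the highest other giving 24, so chance can be excluded for this count. Of 32 splits that part all same-number pairs, 1 (the real one) did, the highest other giving 0. With the replicate block within window the real split gave 222 genes and the highest other 48.

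With both transgenes 146 effects differed between windows. CG14567 (2.38 ± 0.22), Uhg1 (1.94 ± 0.29), CG31445 (1.92 ± 0.32), Wnt6 (1.84 ± 0.22) and E(spl)m7-HLH (1.59 ± 0.27) had higher effects late. CG13159 (-4.46 ± 0.75), CG13920 (-4.05 ± 0.35), CG14756 (-3.49 ± 0.67), CG14110 (-2.86 ± 0.76) and CG4306 (-2.78 ± 0.18) had lower ones. The same limit applies to these 5, with CG4306 at 4.07 to 4.13 log2 units in early control arrays, and Uhg1 rests on its early control level as above. CG14110 lost its call without any 1 of 10 arrays, the exceptions being late control replicate 3 and late combined replicate 2 (adjusted p up to 0.16), in fits on only the groups compared (0.082) and after array median centring (0.060). Chance can be excluded for the count as well, with 1 of 100 regroupings as large and 3 as the highest other. Of 32 splits that part all pairs 1 was as large, with 0 as the highest other. With the replicate block within window these splits gave 338 genes for the real one and at most 18 for the others. The count was 86 without early control replicate 1, 84 without early control replicate 3, 89 without late control replicate 2, 97 without early combined replicate 2, and 96 without early or late combined replicate 3.

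With activated Ras 4 effects differed. Those of Uhg1 (1.78 ± 0.29) and of the mesoderm gene twi (1.06 ± 0.18) were higher late, and those of CG13064 (-1.34 ± 0.16) and PheRS-m (-1.14 ± 0.17) lower. CG13064 lay at background in early control arrays (3.93 to 3.99 log2 units), so an early fall could not have been seen. Uhg1 rests on its early control level as above. Uhg1 lost its call without late Ras replicate 2 (adjusted p = 0.054), and twi without early control replicate 1, late control replicate 2 or 3, early Ras replicate 3 or late Ras replicate 2 or 3 (up to 0.073). In fits on only the groups compared, Uhg1 (0.21), twi (0.077) and PheRS-m (0.077) were not called, and 2 genes were, both lower. The count was 9 without late control replicate 1 and 2 without late Ras replicate 2. Of 100 regroupings 7 gave as many genes and the highest other gave 22, several times the real count, which points to structure among the samples. That structure goes with the replicate numbers, since of 32 splits that part all same-number pairs only 1, the real one, gave as many and the others gave 0. Chance is excluded only where the numbers pair the arrays, which the labels do not state.

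CG13159, CG13920, CG14756, CG14110 and JhI-26 all rose between windows in control embryos, by 2.96 to 5.21 log2 units, and the late Notch effect ran against that change across genes. Its correlation across genes with the change between windows in Ras arrays, which share no array with it, was -0.369 (-0.417 to -0.318), so shared control arrays do not account for the pattern. A delay of the whole embryo is argued against as the full cause. Genes called as rising between windows in Ras arrays, by at least 1 log2 unit, were held back by 36.9% (29.3 to 43.6, 296 genes). Those called as falling there were held back by 6.7% (-0.1 to 15.7, 55 genes), a ratio of 0.181 (-0.003 to 0.447). A delay was taken to hold both back alike, with no allowance for the floor, near which changes are understated. The ranges in parentheses are 95% intervals over genes, which are not independent replicates, and do not measure the spread between arrays. A loss of late differentiation in particular tissues under activated Notch may explain the pattern and was not tested, so it remains a hypothesis.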

How the results depend on the processing

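The fits of 1 window at a time and their form with a replicate block were chosen after the data were seen, and the tests under the other settings before. No named gene called in a comparison changed sign under any setting. The balance of higher and lower calls turned with scaling for Notch late (460 and 404 after array median centring, against 357 and 430), for the change between windows (895 and 1109, against 1049 and 749), for both transgenes late (430 and 457, against 438 and 431) and for Ras late (57 and 85, against 63 and 61). For both against Ras late it turned after quantile normalisation (373 and 361, against 290 and 358). Counts within 1.5 times the main count are not listed, and the cause of a move was not tested unless fewer genes, fewer arrays or a stricter criterion gives it.

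Counts are given in the order Notch, Ras and both against control. A minimum log2 change of 1 gave 125, 10 and 139 early and 228, 36 and 261 late. It gave 5 and 29 for both against Notch (early, late), 159 and 201 for both against Ras, 408 for the change between windows, 54 and 85 for the differences of Notch and combined effects, and 3 and 13 shared genes. The replicate block within window called 495, 44 and 729 early, and 1231 and 281 for Notch and Ras late. It called 46 and 211 for both against Notch, 1128 and 1072 for both against Ras, 36 and 28 for the interaction, 222, 18 and 338 for differences between windows, and 23 and 171 shared genes. A filter at log2 7, which tests fewer genes, gave 12 for Ras early, 501, 71 and 519 late, 4 for both against Notch early, 421 and 389 for both against Ras, 1 and 4 for the interaction, 48, 1 and 78 for differences between windows, and 5 and 45 shared genes. Fits on only the groups compared gave 11 for Ras and 613 for both early, 520, 22 and 558 late, 6 and 34 for both against Notch, 351 for both against Ras late, 4 for the late interaction, 2 for the difference of Ras effects, and 4 and 12 shared genes. The replicate block gave 32 and 203 for Ras, 27 for both against Notch early, 21 for the early interaction, 142, 8 and 235 for differences between windows, and 14 and 119 shared genes. With 1 fit per window Ras late gave 75, both against Notch late 55, the late interaction 4 and the late shared genes 44. With a replicate block in those fits Ras early gave 38, both early 671, both against Notch early 26, both against Ras early 1012, and shared genes 21 and 113. Quantile normalisation gave 4 for the early interaction and 13 for the difference of Ras effects, no filter 22 for the late interaction and 15 for that difference, and array median centring 7 for that difference.

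Leaving out 1 array moved some counts by over 1.5 times; the arrays are named beside each result in the report, and the lowest and highest values follow. Ras early ranged from 10 to 16, both against Notch from 8 to 23 early and from 59 to 116 late, and both against Ras early from 376 to 539. The interaction ranged from 3 to 13 early and from 7 to 17 late. Differences between windows ranged from 59 to 113 for Notch, from 2 to 9 for Ras and from 84 to 170 for both. Shared genes ranged from 4 to 9 early and from 46 to 67 late, and the correlation of Notch and Ras effects from 0.0856 to 0.285 early and from 0.1112 to 0.3098 late.

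Gene lists were counted by the number of comparisons in which they were called. Of 102 calls in all, 36 held with an estimated correlation and 94 with the replicate block. Fry, which asks whether a list changes at all and not whether it differs from other genes, passed 78 of them in 1 direction and 72 in either. With an estimated correlation the numbers were 6 against 11 for Enhancer of split, 1 for Bearded, 0 for Notch pathway, 0 for other Notch-responsive, 5 for proneural, 0 for neuronal, 0 for glial, 0 for RTK-Ras pathway, 3 for mesoderm, 0 for muscle structural, 0 for tracheal, 0 for epidermal, 2 for hemocyte, 0 for gut and 1 for segmentation genes. Fry in either direction called 154 in all: Bearded 0, Notch pathway 9, other Notch-responsive 10, neuronal 6, glial 9, RTK-Ras pathway 10, mesoderm 13, muscle structural 2, tracheal 9, cell cycle 6, gut 7 and segmentation 11. Fry in 1 direction gave Enhancer of split 7, Notch pathway 3, neuronal 3, glial 2, mesoderm 5, muscle structural 4, tracheal 8, epidermal 4, cell cycle 5 and segmentation 8. The replicate block gave Notch pathway 2.

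Of 618 called pairs of a named gene and a comparison, 599 kept the call after array median centring, 595 after quantile normalisation, 572 without a filter, 614 with a trend and robust prior, 614 with all probe sets, 492 with only the groups compared, 395 at a log2 change of 1 and 617 with the replicate block, which ended gcm in the late interaction (adjusted p = 0.051) and no other named call. The filter at log2 7 kept 398 of 400, the replicate block within window 544 of 544, 1 fit per window 409 of 486 and its block 473 of 486, and leaving out 1 array 3580 of 4158. Signal over background limits the depth, since genes near the floor change less than their transcripts.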

Other observations

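In this part, the tests of genes moved alike by Notch and Ras and of glycolytic genes were chosen after the result was seen. So were the tests on splits that part all pairs in the interaction. The test of gene families was chosen after the data were seen, and the other tests before. The levels of nau, kn, Kr, hry and Wnt6 in the next paragraphs were picked after the tables were seen and are given as values.

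The MyoD-family gene nau, raised by Ras, stayed low when Notch was active as well. It stood at 5.59 ± 0.66 log2 units in late Ras arrays, 3.83 ± 0.19 in control, 3.36 ± 0.06 in Notch and 3.52 ± 0.21 in combined arrays (SD, n = 3). Its departure from the sum of single effects was -1.61 ± 0.36 and was not called (adjusted p = 0.090). The opposite effects on kn showed no called departure from their sum. It stood at 7.23 ± 0.75 in late Ras, 6.12 ± 0.31 in control, 3.46 ± 0.06 in Notch and 4.75 ± 0.13 in combined arrays, 0.17 ± 0.35 from the sum (adjusted p = 0.998). Both sums are inexact, since nau and kn lay near background in late Notch arrays. twi, which both transgenes raised, stood at 4.42 ± 0.16, 5.19 ± 0.07, 5.92 ± 0.09 and 6.62 ± 0.14 in late control, Notch, Ras and combined arrays.

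The segmentation genes Kr and hry were lowered by Notch but differed in what Ras did beside it. Late Kr was at 7.00 ± 0.16 in control, 4.61 ± 0.49 in Notch and 6.06 ± 0.20 in combined arrays, 1.45 ± 0.20 higher with Ras added. Late hry fell further with Ras added, from 7.64 ± 0.10 in Notch to 6.09 ± 0.15 in combined arrays, against 8.38 ± 0.15 in control. Neither departure from the sum of single effects was called (1.01 ± 0.28 for Kr, adjusted p = 0.28; -0.63 ± 0.22 for hry, adjusted p = 0.67). Wnt6 lay between 3.37 and 3.48 in the groups other than late Notch (5.48 ± 0.46) and late combined (5.29 ± 0.27).

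Gene families grouped by symbol were tested as well, and camera with an estimated correlation passed 0 of 832 tests (52 families in 16 comparisons) after adjustment, with 35 at an unadjusted p under 0.05.

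Arrays of 1 replicate number deviated together from their group means within a window, with a median correlation across genes of 0.409. After the axis of change between windows was removed, 92.5% of that correlation was kept (91.8% early and 102.6% late). That axis held only 4% of the spread within groups. The deviations thus lay mostly off it, and a difference in developmental age between collections along this axis accounts for little of the correlation. Age differences along another axis were not tested. Removal of each array's trend with mean level took out 2.9% of the spread, and 100.2% of the correlation was kept (99.8% early and 98.2% late). GCRMA by default takes out such trends beforehand, so the removal tested only what was left of them. A difference in overall intensity before that step cannot be told apart. A day or experiment shared by arrays of 1 number could explain the correlation and was not tested, since the labels give no dates.

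Notch and Ras moved 53 genes the same way late. A common difference of the control cross from all transgenic crosses, as the only cause, needs a combined effect of 0.5 times the sum of single effects. The median ratio was 0.749 (0.706 to 0.775), which argues against it as the only cause. Whether such a difference contributes in part cannot be told from this ratio. Chance values of the shared control arrays gave as many genes in 0 of 100 simulations with unchanged groups (at most 2) and in 0 of 100 with called effects only (mean 14.81, at most 22). The first decides little, since unchanged groups gave only 1.98 Notch and 1.4 Ras calls on average. Both drew every gene and array independently, so deviations that same-number arrays or many genes share could not arise in them and are not excluded. An earlier simulation that shuffled all Ras estimates gave as many in 100 of 100, but made 610.67 Ras calls on average against 124 and so decides nothing. Without control arrays, 92.5% (81.8 to 97.9) of the genes moved the same way when Ras was added to Notch and 94.3% (84.3 to 98.8) when Notch was added to Ras. The ranges given here are 95% intervals over genes, which are not independent replicates, and do not measure the spread between arrays. Whether a delay of the whole embryo contributes cannot be told apart from direct effects, since 62.3% (47.9 to 75.2) of the genes followed a delay by the change in combined arrays, which carry the effect itself, and 83% (70.2 to 91.9) by that in control arrays, which are shared.

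Glycolytic genes were lower late with each transgene, a hypothesis raised by Gapdh1 and Eno. Of 13 listed genes 7 were measured, and the highest adjusted p of the 3 late comparisons was 0.01196 (camera, estimated correlation), with medians of -0.535 for Notch, -0.277 for Ras and -0.580 for both. The list held the genes that raised the question, so the test is not independent of it. Early, 0 of the 7 were called in the limma fit, and the set p was 0.81, 0.95 and 0.95. Late, 4, 1 and 4 were called lower, and Eno changed by -0.54, -0.99 and -1.33. Lower glycolytic transcription may be common to the crosses. The 3' minus 5' difference of the GAPDH control probe sets moved with it, at 3.17 in late control, 1.61 in Notch, 2.45 in Ras and 1.98 in combined arrays. In the same order the difference was 0.645, 0.619, 0.469 and 0.431 for actin and 1.82, 1.86, 1.67 and 1.76 for the eIF-4a control probe sets. Both differed from late control by less than the SD of the control arrays (0.262 and 0.205), and so give no sign of a difference in RNA quality. A difference in RNA quality that only GAPDH shows, or of the control arrays that these 3 comparisons share, stays open.

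Comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05, and in each the real split alone (1 of 10) gave as many genes. The real count and the highest other were 311 and 0 for Notch early, 21 and 0 for Ras early, 399 and 0 for both early, 787 and 2 for Notch late, 124 and 73 for Ras late, and 869 and 31 for both late. They were 13 and 0 for both against Notch early, 105 and 1 late, 632 and 0 for both against Ras early, 648 and 87 late, and 1798 and 0 for the change between windows. Where the numbers pair the arrays, the 3 other splits that part all pairs gave 0 genes in each comparison, and the higher values came from splits that keep pairs together. For the early interaction 1 of 100 regroupings, the real one, gave as many genes (8 against at most 5), so regrouping these arrays seldom gives that count. The count itself is fragile, at 4 after quantile normalisation and 1 with a filter at log2 7. It also includes CG31445, Dgat2 and Uhg1, for which the sum is not known or could not have been shown. For the late interaction 10 of 100 did (13 against at most 154), and 154 calls point to structure among the samples. Those regroupings ignore the replicate numbers. Of 32 splits that part all same-number pairs, as the real one does, 1 (the real one) gave as many genes in each window, and the others gave 0. With the replicate block within window the late count was 28 against at most 2. Chance is therefore excluded for the late count only where the numbers pair the arrays, which the labels do not state.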
